A study of Mus musculus with 12 samples.

How the data were processed

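Gene expression was measured by RNA sequencing in 12 libraries of EO771, a mouse breast cancer cell line, 4 separate cultures for each of 3 short hairpin RNA groups. Every library carries sgPcsk9 in its label, a guide RNA named for Pcsk9. The groups are sh002, shLrp1-1 and shLrp1-3, and sh002 served as the reference because it is the hairpin not named for Lrp1. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made with a TruSeq RNA kit from polyA RNA.

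The deposited table holds raw counts per gene, 1 column per library and 16533 gene symbols. Reads were mapped with STAR 2.7.10b to GRCm38 and counted with featureCounts 2.0.6, per the submitters' processing notes. The annotation used for counting, the strand setting and the rule for reads that map to several places are not given in the sources used here. The values were checked to be whole numbers, and every symbol has a count above 0 in at least 4 of the 12 libraries. No mitochondrially encoded transcript is among the symbols. Of the symbols, 16527 matched a RefSeq gene of GRCm38.p6, which gave identifiers, coordinates and gene types (14617 protein-coding genes, 1362 long non-coding RNAs, 241 microRNAs). A GC content and length, those of the longest GENCODE M21 transcript, were available for 16222. All 695 members of the gene lists found in the count table had both values.

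Total counts per library ran from 13709110 to 76377403. The limit that a count of 0 allows, taken as 3 counts, lay between 0.0393 and 0.219 CPM (counts scaled to library size). It covers counting error only, since reads without molecular identifiers are not independent molecules. Replicates differed by more than counting noise, with a chi-square per gene of 1.8 to 25.8 between libraries of 1 group, so all tests used the spread between cultures. Each hairpin was represented by cultures that share a hairpin, and the p-values describe the spread between those cultures, not between independently made hairpin lines.

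Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12319 genes and set aside 4214 that held at most 0.043% of the counts of any library. TMM factors scaled the libraries. All 12 libraries entered 1 robust quasi-likelihood model with a coefficient per group and no further terms, and the tests compared shLrp1-1 with sh002, shLrp1-3 with sh002, and shLrp1-3 with shLrp1-1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12319 genes. Genes changed with both hairpins were those called in both tests against sh002 with the same sign. Because those tests share the 4 control libraries, the overlap was set beside 50 simulated sets without any changed gene and beside 6 ways of splitting the controls between the hairpins. CPM values are TMM-scaled means ± SD, and log2 values per library used a prior count of 2. Single genes fixed in advance were also compared by an exact two-sided permutation test of log2 CPM over the 70 assignments of 4 against 4 libraries, whose smallest p is 0.0286.

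Gene lists were written before the data were examined, as were the groups, the tests and the rule for named genes. The 28 lists cover type I interferon-stimulated genes, antigen presentation and interferon-gamma response, the LDL receptor family, LRP1 ligands, cholesterol biosynthesis, fatty acid and lipid synthesis, cholesterol efflux and LXR targets, lysosome and endocytosis, cell division, DNA replication, p53 targets, hypoxia and glycolysis, the integrated stress response (ATF4 targets), the unfolded protein response, NF-kB and inflammatory cytokines, extracellular matrix and collagens, matrix proteases and inhibitors, mesenchymal state, epithelial and mammary state, TGF-beta and YAP targets, Wnt targets, dsRNA sensing and small RNA machinery, immediate early genes, markers of immune, endothelial or adipocyte, and fibroblast or pericyte cells, mitochondrially encoded transcripts, and nuclear-retained or non-polyadenylated RNAs. The lists overlap in members. Lists with at least 5 tested members (27 lists, all but the mitochondrial list) were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 27 lists. Camera with a correlation estimated for each list, and fry, were run beside it. List scores per library are the mean log2 CPM of the members relative to the sh002 mean.

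Except where stated, the genes named in the text follow this rule: Lrp1, Pcsk9, Xaf1 and Usp18 always; among genes called in the same direction with both hairpins at a mean of at least 5 CPM, the 8 in each direction with the largest smaller change; for each comparison, the 5 in each direction with the largest change among called genes at that level, with all libraries of 1 group on the same side of the other; and in each list up to 4 called members per comparison with the smallest adjusted p. Unnamed gene models were passed over. Not every gene that met the rule is printed.

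Alternatives fixed in advance were DESeq2 size factors in edgeR, library totals without TMM, the DESeq2 1.42.0 Wald test, no low-count filter, a mean count of at least 50, a model of only the compared groups, the replicate number as a block, leaving out each library in turn, and, for lists, the estimated correlation and fry. Added after the data had been seen were offsets per library for GC content and length (splines with 5 degrees of freedom over genes of at least 1 CPM), each library's score on the first component of the within-group deviations as a covariate, and a model without the 4 libraries farthest out on that component. Comparisons of each result with other splits of the same libraries are given with the closing observations.

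Each step across genes was tested on simulated data drawn from the real means and library sizes. For shLrp1-1 against sh002, over 12319 genes, 54% of genes changed 1.25-fold were recovered, 88% at 1.5-fold, 92% at 2-fold and 100% at 4-fold. Of all calls there, 6.18% were false, and simulated shLrp1-3 libraries without a changed gene gave 0 calls against sh002. Genes were drawn independently of each other in these runs, so the rates leave out variation that genes of the real libraries share.

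Left out were the 4214 weakly counted genes, isoforms and splicing, which gene counts do not resolve, and any test of the guide RNA, since no library lacks it. Genes with close copies (Oas1a and its tandem copies, Oasl1 and Oasl2, Acta2 and Actg2, Tubb2b, Ly6c1, and the histone gene H1f2) are uncertain to the extent that reads were shared between copies. Exons of other genes overlap more than 10% of the exonic bases of only 1 of the named genes, Ctsb, where 12.8% are overlapped by Fdft1 on the opposite strand.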

Results

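RNA sequencing counts were collected from 12 cultures of EO771, a mouse breast cancer cell line, in 3 groups of 4 cultures. The groups carried the control hairpin sh002 or a hairpin against Lrp1, shLrp1-1 or shLrp1-3, and all 12 libraries were labelled sgPcsk9. Lrp1 encodes LDL receptor-related protein 1, an endocytic receptor for many extracellular ligands, and the stated purpose of the series was to learn how LRP1 affects gene expression in breast cancer cells. Total counts of replicates 1 to 4 were 27.3, 25.2, 31.7 and 49.6 M counts for sh002. They were 20.9, 20.1, 23.3 and 76.4 M for shLrp1-1, and 13.7, 59.5, 27.4 and 26.7 M for shLrp1-3. At these depths a count of 0 allows between 0.0393 and 0.219 CPM (counts scaled to library size), counting error only. The 10 most abundant genes took 4.82% to 5.17% of the counts of a library. Within groups, libraries differed along a component that held 65.6% of the within-group variance and whose gene weights followed GC content across genes (Spearman 0.68 over 9380 genes, which are not independent replicates).

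Lrp1, the targeted gene (gene ID 16971, GRCm38 chromosome 10, 127538157 to 127621148, protein-coding), was lower in every hairpin library than in every sh002 library. Replicates 1 to 4 of sh002 had 484, 601, 531 and 586 CPM. Those of shLrp1-1 had 244, 272, 291 and 292 CPM, and those of shLrp1-3 had 149, 145, 167 and 151 CPM. The means were 550 ± 53.3 CPM in sh002, 275 ± 22.6 in shLrp1-1 and 153 ± 9.62 in shLrp1-3 (SD, n = 4 each). Lrp1 fell to 50% of the control level with shLrp1-1 (log2 fold change −1.0, SE 0.07, edgeR adjusted p = 6.77e-07) and to 27.8% with shLrp1-3 (−1.85, SE 0.07, edgeR adjusted p = 2.48e-09). It was lower with shLrp1-3 than with shLrp1-1 (−0.85, SE 0.07, edgeR adjusted p = 4.33e-06). The exact two-sided permutation test gave p = 0.0286 for each of these comparisons, the smallest it can give. Pcsk9 (gene ID 100102, chromosome 4, 106442334 to 106464325), which encodes a secreted protein that promotes LDL receptor degradation and is named in every label, was measured at 231 ± 1.84, 223 ± 4.82 and 237 ± 11 CPM (SD, n = 4 each) and was not called in any comparison (edgeR adjusted p = 0.324, 0.552 and 0.116). Its 4 shLrp1-1 libraries (218 to 229 CPM) nevertheless all lay below the 4 sh002 libraries (230 to 234 CPM), a log2 fold change of −0.05 with exact permutation p = 0.0286, and the exact p was 0.343 for shLrp1-3 against sh002 and 0.0571 between the hairpins. The guide was present in all groups, so its effect was not measured, and gene counts do not show edits.

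**Figure D1:**
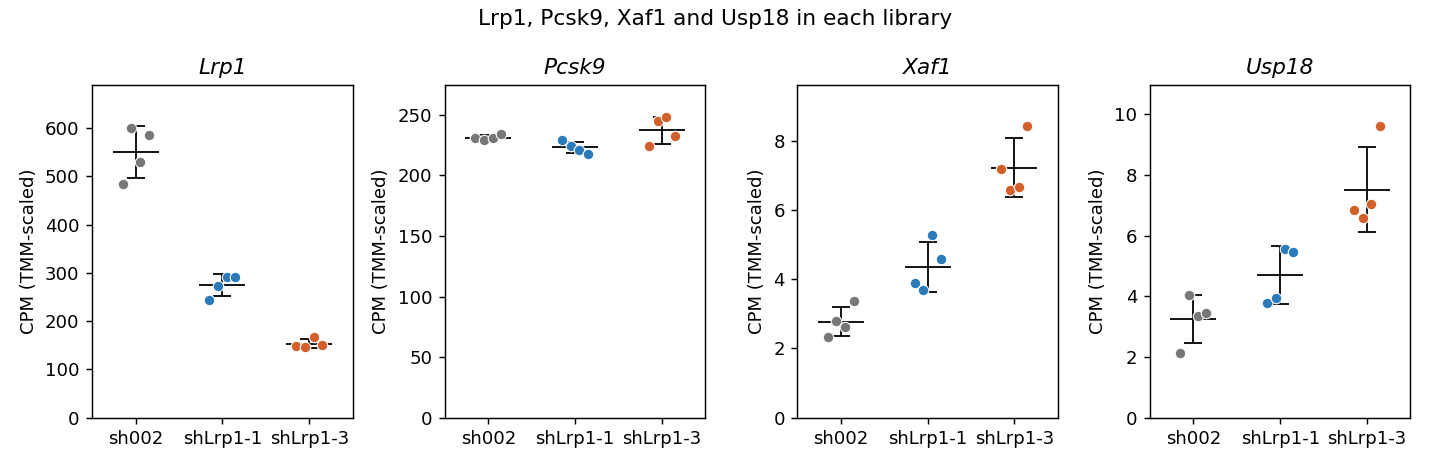
TMM-scaled CPM (linear axes from 0) of Lrp1, Pcsk9, Xaf1 and Usp18 in the 3 groups, with a point per library and black bars for the mean ± SD (n = 4). Lrp1 libraries lie between 484 and 601 CPM with sh002, 244 and 292 with shLrp1-1 and 145 and 167 with shLrp1-3, while Xaf1 and Usp18 have their highest values with shLrp1-3.

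The comparison of shLrp1-1 with sh002 asked which genes differed in cells with Lrp1 at 50% of the control level. Of 31 genes for collagens and other matrix proteins, 11 fell, and of 19 genes for matrix-degrading proteases and their inhibitors, 9 rose. Col3a1, the chain of type III collagen and an abundant transcript, went from 3337 ± 92.7 to 1969 ± 54.6 CPM (SD, n = 4 each; log2 fold change −0.76, SE 0.05). Acta2, the smooth muscle actin of contractile cells (chromosome 19, 34240336 to 34255585), went from 176 ± 12.2 to 92 ± 11.6 CPM (−0.94, SE 0.08). Serpine1, the plasminogen activator inhibitor PAI-1 and a ligand of LRP1, went from 62.6 ± 3.81 to 102 ± 2.08 CPM (0.71, SE 0.05).

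Of 19 tested members of the list of matrix proteases and inhibitors, 9 rose, 0 fell and 10 did not pass, and 9 rose when adjusted over the list alone. Besides Serpine1 they included Mmp9 (0.51), Plau, the urokinase gene (0.39), and Mmp3, the stromelysin gene, which was weakly expressed and went from 0.499 ± 0.2 to 2.76 ± 0.635 CPM (2.60, SE 0.25). Of 31 tested matrix and collagen genes, 11 fell, among them Col6a2 (−0.58) and Thbs2 (−0.49), 2 rose and 18 did not pass, with 16 lower and 3 higher when adjusted over the list alone. The median of this list was −0.20, and it was −0.08 with offsets for GC content and length, where 11 fell and 6 rose (camera adjusted p = 0.000557). Fold changes in this comparison followed GC content across genes (Spearman −0.33, 0 with the offsets). Of 11 fibroblast and pericyte markers, which are collagen genes in part, 6 fell and 1 rose, and 4 did not pass, with 7 lower and 1 higher when adjusted over the list alone. With the offsets 4 of these markers fell and 3 rose (median −0.30 in place of −0.23, camera adjusted p = 0.00892). Dpt, a matrix protein gene of fibroblasts, was among those that fell (−0.23). Camera called all 3 lists (adjusted p = 6.47e-08, 3.97e-07 and 0.000543), and the calls held with an estimated correlation (adjusted p = 0.0311, 0.0362 and 0.0362).

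Of 21 fatty acid and lipid synthesis genes, 11 did not pass and 9 fell, among them the desaturase genes Fads2 (−0.30) and Scd2 (−0.24), and Lpin2 rose (0.33), with 10 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00303, and 0.0362 with an estimated correlation). Of 25 cholesterol biosynthesis genes, 16 did not pass, 9 fell and 0 rose, among them Srebf2, the master regulator of the pathway (−0.34), and Fdps (−0.25), with 9 lower and 1 higher when adjusted over the list alone. That list was called with camera (adjusted p = 0.0441) but not with an estimated correlation (adjusted p = 0.574 with an estimated correlation), and its scores per library overlapped between the groups (exact permutation p = 0.343, n = 4 each). Its call was also lost without sh002 replicate 1 (adjusted p = 0.266), sh002 replicate 3 (0.0523), shLrp1-1 replicate 2 (0.0576) or shLrp1-1 replicate 3 (0.079), with a mean count of at least 50 (0.0707) and with only the compared libraries (0.0527).

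Of 48 type I interferon-stimulated genes, 17 rose, 3 fell and 28 did not pass, and 22 rose and 4 fell when adjusted over the list alone (median 0.27). Replicate 1 of sh002 had a lower list score (−0.22) than the other control libraries (0.058 to 0.085), and without it 15 rose and 4 fell (median 0.20, camera adjusted p = 0.00376). Oasl1 (0.75) and Ifih1, which encodes the dsRNA sensor MDA5 (1.16), were among those that rose, and Samhd1 (−0.27) among those that fell. Xaf1 and Usp18, interferon-induced genes that the study is known to have followed up from these samples, are members, so the list is not independent evidence of its direction. Without them, 15 of 46 rose and 3 fell. Xaf1 rose by 0.64 (SE 0.14, edgeR adjusted p = 0.00435) and Usp18 by 0.56 (SE 0.19, edgeR adjusted p = 0.0405). The exact permutation test gave p = 0.0286 for Xaf1 but p = 0.0857 for Usp18, whose libraries overlapped (3.79 to 5.58 CPM against 2.15 to 4.05 in sh002, n = 4 each). The Usp18 call was lost without sh002 replicate 1 (adjusted p = 0.0702), 3 (0.0695) or 4 (0.0729), without shLrp1-1 replicate 3 (0.103) or 4 (0.169), and without the 4 libraries farthest out on the GC-linked component (0.208). Of 29 immediate early genes, the rapid transcriptional responders to signalling, 10 rose and 0 fell (17 and 2 with GC and length offsets), with 12 higher when adjusted over the list alone, including Egr3 (0.82) and Dusp5 (0.56). Of 31 NF-kB and inflammatory cytokine genes, 12 rose, including the chemokine gene Ccl7 (0.78), and 3 fell, including the complement gene C3 (−0.62), with 12 higher and 4 lower when adjusted over the list alone. Camera called the interferon, immediate early and NF-kB lists (adjusted p = 4.34e-05, 7.06e-06 and 0.00266), and none of these calls held (adjusted p = 0.574, 0.26 and 0.291 with an estimated correlation).

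Among single genes outside these lists, Il18rap (1.245), Il1rl1, which encodes the interleukin-33 receptor (1.08), the Notch ligand gene Dll1 (1.04) and Shank2 (0.96) were among the largest increases. Inpp5j, which encodes an inositol polyphosphate phosphatase (−1.39), Cbr2 (−1.23) and the matrix gene Prelp (−1.12) were among the largest decreases. In all, edgeR called 2910 of 12319 genes (1264 higher, 1646 lower), 164 of them by at least 2-fold (137 higher, 27 lower), with a median absolute log2 fold change of 0.28. The groups did not overlap for 27.1% of genes, where chance gives 2.86%. With library totals in place of TMM, 67.5% of the called genes were higher (2077 against 1002) in place of 43.4%, so the split between directions depended on the scaling. The count was 1819 without shLrp1-1 replicate 4.

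The comparison of shLrp1-3 with sh002 asked the same of cells with Lrp1 at 27.8% of the control level. Of 48 interferon-stimulated genes 29 rose, of 30 antigen presentation genes 13, and of 31 stress response genes 18. Xaf1 (chromosome 11, 72301461 to 72313733) went from 2.78 ± 0.432 to 7.22 ± 0.855 CPM (log2 fold change 1.35, SE 0.13, edgeR adjusted p = 8.81e-06) and Usp18, which encodes a protease that removes ISG15 from proteins (chromosome 6, 121245906 to 121270917), from 3.25 ± 0.798 to 7.51 ± 1.4 CPM (1.20, SE 0.18, edgeR adjusted p = 0.000372; SD, n = 4 each; exact permutation p = 0.0286 for each). Atf3, a stress-induced transcription factor gene (chromosome 1, 191170296 to 191183333), went from 40.4 ± 2.29 to 75.7 ± 1.89 CPM (0.90, SE 0.05). Of 32 genes of the mitotic machinery, 10 fell, by smaller amounts.

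Of 48 type I interferon-stimulated genes, 29 rose, 0 fell and 19 did not pass, with 33 higher and 1 lower when adjusted over the list alone (median 0.60). The 2 genes that the study chose on these samples are again among them, and without them 27 of 46 rose. The antiviral genes Zbp1 (1.5), Oasl2 (1.32) and Oas1a (1.27) were among those that rose, all from a low level, with Oasl2 at 5.95 ± 0.635 CPM in sh002 and 14.9 ± 1.59 CPM in shLrp1-3 (SD, n = 4 each). Of 30 antigen presentation and interferon-gamma response genes, 13 rose and 0 fell, with 16 higher when adjusted over the list alone, including Gbp2 (1.37), Cd274, which encodes the checkpoint ligand PD-L1 (1.29), and the immunoproteasome gene Psmb8 (0.32). Ifnb1, the interferon beta gene, had 41 counts in all libraries together, with a count in 9 of them. Its group means were 0.0391 (sh002), 0.105 (shLrp1-1) and 0.132 CPM (shLrp1-3). The counting limit holds for a single library and is not a limit for such means. The filter set the gene aside for its few counts, so whether it differed between the groups was not tested. Summed CPM of immune cell markers was 12.4 ± 0.67 in sh002, 16.3 ± 0.546 in shLrp1-1 and 15.9 ± 1.16 in shLrp1-3, against 1530 ± 99.8, 1560 ± 58.3 and 1780 ± 110 for the interferon-stimulated genes (SD, n = 4 each).

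Of 31 integrated stress response genes (targets of the transcription factor ATF4), 18 rose and 0 fell, with 21 higher when adjusted over the list alone (median 0.23). Besides Atf3 they included Ppp1r15a, which encodes the phosphatase subunit GADD34 (0.84), Ddit3, the CHOP gene (0.80), and Trib3 (0.65). Of 26 p53 target genes, 7 rose and 1 fell, with 9 higher and 1 lower when adjusted over the list alone, including Gdf15 (0.78) and the cell cycle inhibitor gene Cdkn1a (0.40). Of 30 TGF-beta and YAP targets, 13 rose and 4 fell, with 14 higher and 4 lower when adjusted over the list alone, including Ccn1 (0.88) and Id2 (0.79). Of 28 LRP1 ligand genes, 11 rose and 4 fell, with 12 higher and 4 lower when adjusted over the list alone, including Plat, the tissue plasminogen activator gene (0.65), and Plau (0.41) among those higher and C3 (−1.19) among those lower. Of 19 matrix protease and inhibitor genes, 7 rose and 0 fell, with 7 higher when adjusted over the list alone. They are mostly ligand genes too, such as Serpine1 (0.51). Of 12 members of the list of nuclear-retained or non-polyadenylated RNAs, 5 rose and 0 fell, with the same counts when adjusted over the list alone. They included the linker histone gene H1f2 (0.82) and the long non-coding RNA Gas5 (0.32). Membership rests on the list as written beforehand, and neither the location nor the polyadenylation of these RNAs was measured. Of 21 fatty acid and lipid synthesis genes, 3 fell, including Scd2 (−0.33), and 1 rose, with 5 lower and 1 higher when adjusted over the list alone.

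Camera called the interferon-stimulated (adjusted p = 7.33e-25), antigen presentation (8.7e-11), ATF4 (9.09e-23), p53 (0.000144), TGF-beta and YAP (0.000121), LRP1 ligand (5.26e-05), protease (9.08e-06), nuclear RNA (0.000121) and fatty acid (0.007) lists. These 9 calls held with an estimated correlation (adjusted p from 0.0267 to 0.0435). The remaining 3 did not hold. Of 29 immediate early genes, 14 rose, including Klf2 (0.86), and 1 fell, with 15 higher and 1 lower when adjusted over the list alone (camera adjusted p = 4.51e-11, adjusted p = 0.0635 with an estimated correlation). Of 31 NF-kB and inflammatory cytokine genes, 9 rose, including Ptgs2, the cyclooxygenase-2 gene (1.16), and Csf1 (0.36), and 2 fell, with 13 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00118, adjusted p = 0.211 with an estimated correlation). Of 32 cell division genes, 10 fell and 0 rose (18 and 0 with GC and length offsets, adjusted p = 1.86e-07), with 11 lower when adjusted over the list alone, including Bub1b (−0.25), Aurkb (−0.21) and Foxm1 (−0.20) (camera adjusted p = 0.000144, adjusted p = 0.228 with an estimated correlation).

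**Figure D2:**
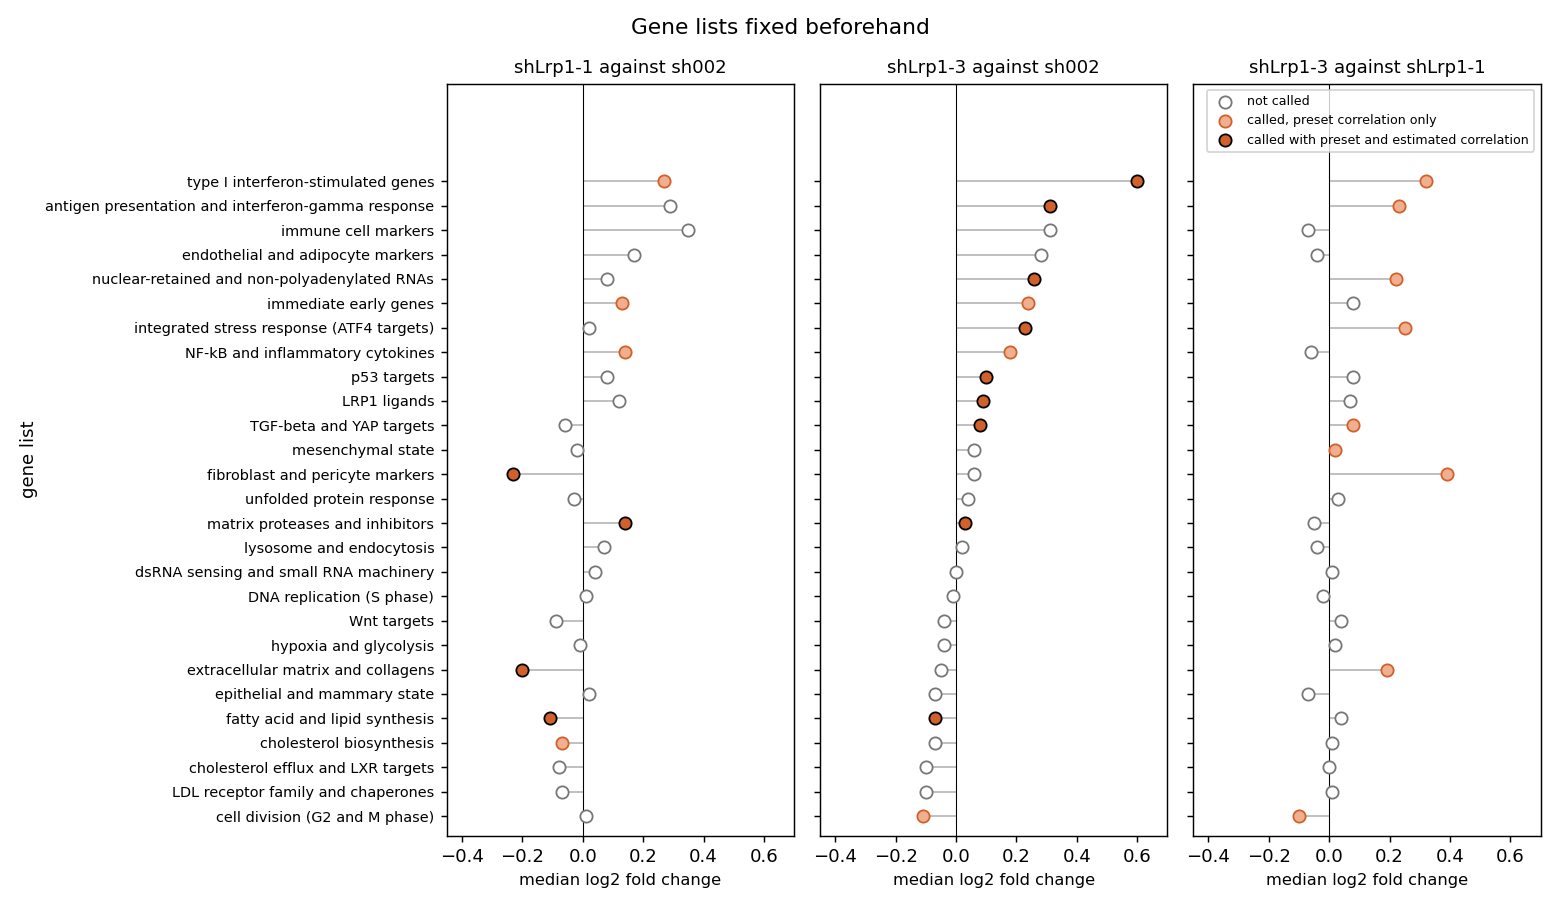
Median log2 fold change of the tested members of the 27 gene lists in each of the 3 comparisons, ordered by the median with shLrp1-3. Filled points were called by camera, dark ones also with an estimated correlation, and open points were not called; interferon-stimulated genes have medians of 0.27, 0.60 and 0.32.

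Single genes with the largest changes included Car6, a secreted carbonic anhydrase gene (1.255), and Krt16, a keratin gene of stressed epithelia (1.245), among those that rose, and Eppk1 (−1.24), C3 (−1.19) and Ly6c1 (−1.17) among those that fell. In all, edgeR called 2184 genes (1045 higher, 1139 lower), 116 of them by at least 2-fold (96 higher, 20 lower), with a median absolute log2 fold change of 0.29. The groups did not overlap for 19.3% of genes, where chance gives 2.86%. With library totals in place of TMM, 62.2% of called genes were higher (1446 against 880) in place of 47.8%. The Spearman correlation of fold changes with GC content across genes was −0.07. With the score on the GC-linked component as a covariate the count was 4536.

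The calls with both hairpins asked which changes were shared by hairpins that have Lrp1 as their common target. Shared increases included Krt16 (chromosome 11, 100246091 to 100248902), at 3.56 ± 0.273 CPM in sh002, 7.01 ± 0.575 in shLrp1-1 and 8.49 ± 0.603 in shLrp1-3 (SD, n = 4 each; log2 fold changes 0.96 and 1.245). The chemokine gene Ccl5 (0.94 and 0.92), the antiviral genes Rsad2 (0.91 and 1.29) and Oasl2 (0.77 and 1.32), and Ptgs2 (0.90 and 1.16) also rose with both, as did Fam171b (0.86 and 0.97) and Calr3 (0.84 and 0.90). Shared decreases included Islr, a secreted leucine-rich repeat protein gene (chromosome 9, 58156246 to 58159236), at 14.1 ± 1.38, 5.97 ± 0.644 and 4.7 ± 0.413 CPM (SD, n = 4 each; −1.252 and −1.58). Septin4 (−1.01 and −0.98), Galnt15 (−0.99 and −0.93) and the tubulin gene Tubb2b (−0.72 and −0.69) fell with both.

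In total 1078 genes were called in the same direction with both hairpins, 448 higher and 630 lower, and 42 of them changed at least 2-fold with both. Independent calls would share 107.2 higher and 152.2 lower. Opposite calls numbered 34, against 256.5 for independent calls. Of the shared genes, 576 had the larger change with shLrp1-3, the hairpin with less Lrp1 left. The difference between hairpins was called for 152 of them, and among these 93 changed more with shLrp1-3 and 59 more with shLrp1-1. Lists called with both hairpins and both correlations were those of matrix proteases (higher) and of fatty acid and lipid synthesis (lower). List scores of the second overlapped between shLrp1-3 (−0.142 to −0.043) and sh002 (−0.046 to 0.027; exact permutation p = 0.0571, n = 4 each), while those of the first did not overlap with either hairpin (exact permutation p = 0.0286 for each). Such separation was common, with 10 (shLrp1-1) and 13 (shLrp1-3) of 27 lists apart from sh002. The smallest exact permutation p after adjustment over the lists was 0.0772 and 0.0594, values fixed by the test's smallest p and the number of lists that reached it. The median of the protease list was 0.14 with shLrp1-1 and only 0.03 with shLrp1-3.

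The comparisons share their 4 control libraries, which alone makes fold changes resemble each other. Fold changes correlated at 0.6 across genes, against a mean of 0.494 and a highest value of 0.527 in 50 simulations without changed genes. With the controls split between the hairpins the correlation was 0.273 to 0.488. Splitting removes the shared control noise and leaves each hairpin fewer controls, so this range is not comparable with the simulated values. The covariance of fold changes was 0.0457, against a mean of 0.00865 in the simulations and 0.0268 to 0.0411 with split controls. Shared calls numbered 0 in the simulations and 454 to 586 with split controls. The simulations drew each gene independently, without the GC-linked component, so neither their 0 nor their correlation and covariance set a bound for real libraries. Other splits of the real libraries gave up to 819 shared calls. With library totals in place of TMM, 63.9% of shared calls were higher (714 against 403) in place of 41.6%. The shared count was 713 without sh002 replicate 2 and 1855 with the GC-linked score as a covariate.

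**Figure D3:**
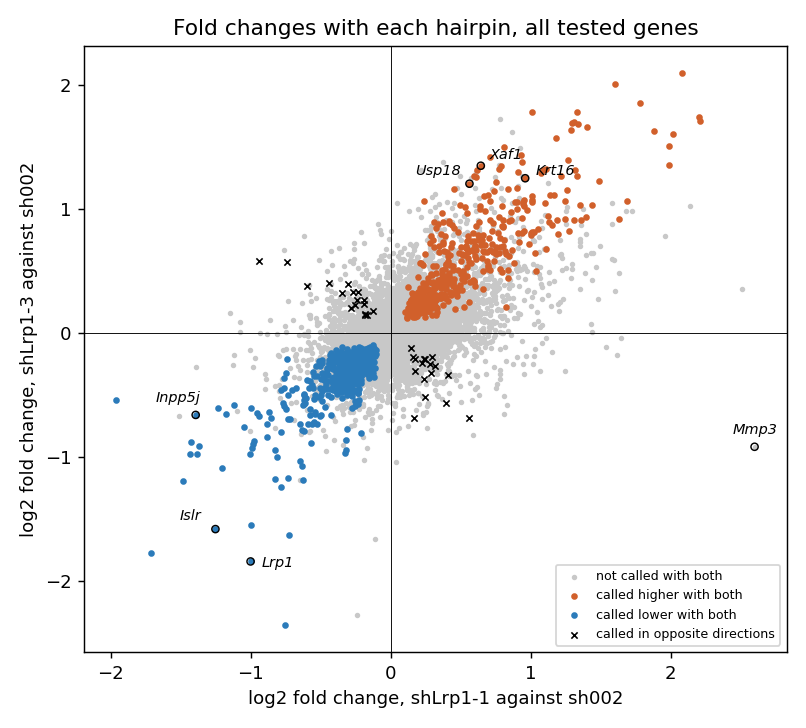
Log2 fold change of each tested gene with shLrp1-1 (horizontal axis) and with shLrp1-3 (vertical axis), both against sh002. The 448 genes called higher and 630 called lower with both are coloured, crosses mark the 34 called in opposite directions, and grey points were not called with both.

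The comparison of shLrp1-3 with shLrp1-1 asked where the hairpins differed, without the controls. Of 31 stress response genes 20 were higher with shLrp1-3, of 48 interferon-stimulated genes 22, and of 31 matrix genes 18. Acta2 was at 175 ± 9.4 CPM with shLrp1-3 and 92 ± 11.6 with shLrp1-1 (SD, n = 4 each; log2 difference 0.94, SE 0.08, edgeR adjusted p = 3.66e-06). Against sh002 its log2 fold change with shLrp1-3 was 0.00 (SE 0.08). Mmp3 (chromosome 9, 7445822 to 7455975) was at 0.258 ± 0.137 CPM with shLrp1-3, close to the counting limit, and 2.76 ± 0.635 with shLrp1-1 (−3.52, SE 0.29, edgeR adjusted p = 3.08e-06). Xaf1 (0.70, SE 0.13, edgeR adjusted p = 0.00216) was higher with shLrp1-3. So was Usp18 (0.64, SE 0.17, edgeR adjusted p = 0.0229), a call lost without shLrp1-1 replicate 1 (adjusted p = 0.0556) or 2 (0.0565), without shLrp1-3 replicate 4 (0.0813) and with the GC-linked score as a covariate (0.077).

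Of 31 ATF4 target genes, 20 were higher with shLrp1-3 and 0 lower, with 23 higher when adjusted over the list alone, including Atf5 (0.63), Trib3 (0.58) and Ppp1r15a (0.52). Of 48 interferon-stimulated genes, 22 were higher and 2 lower, with the same counts when adjusted over the list alone. Without the 2 genes the study chose, 20 of 46 were higher. Of 30 antigen presentation genes, 13 were higher, including Psmb8 (0.67), and 1 lower, with 16 higher and 1 lower when adjusted over the list alone. Of 31 matrix and collagen genes, 18 were higher and 0 lower, with 18 higher and 2 lower when adjusted over the list alone, including Col3a1 (0.40), Lamc2 (0.33) and Thbs2 (0.27). Of 11 fibroblast and pericyte markers, 6 were higher, including Cspg4 (0.71) and Pdgfrb (0.27), and 2 lower, including Dpt (−0.31), with 8 higher and 2 lower when adjusted over the list alone. Of 23 mesenchymal genes, 9 were higher, including Tpm1 (0.38), and 2 lower, with 10 higher and 2 lower when adjusted over the list alone. Of 30 TGF-beta and YAP targets, 12 were higher, including Id2 (0.86), and 2 lower, with 12 higher and 3 lower when adjusted over the list alone. Of 12 nuclear-retained or non-polyadenylated RNAs, 5 were higher, including H1f2 (0.81), with 5 higher when adjusted over the list alone, and 3 higher with GC and length offsets. Of 32 cell division genes, 3 were lower and 0 higher (9 lower with the offsets), with 2 lower when adjusted over the list alone.

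Camera called these 9 lists (adjusted p = 8.66e-18 for ATF4 targets, 2.99e-09 for interferon-stimulated genes, 9.15e-07 for antigen presentation, 5.95e-06 for matrix, 3.67e-05 for fibroblast markers, 0.00781 for mesenchymal genes, 0.000986 for TGF-beta and YAP, 0.00576 for nuclear RNAs and 0.00679 for cell division). None held (in the same order, adjusted p = 0.0817, 0.277, 0.151, 0.0817, 0.0687, 0.164, 0.0817, 0.0817 and 0.512 with an estimated correlation). List scores per library put all 4 shLrp1-3 libraries above all 4 shLrp1-1 libraries or below them for 8 of these 9, cell division being the exception, with exact permutation p = 0.0286 for each of the 8 and 0.0644 after adjustment over the 27 lists. The first is the smallest p this test can give, and the second follows from the 12 of 27 lists that reached it, so it does not speak against any single list. The ATF4 score was 0.30 ± 0.02 with shLrp1-3 and 0.07 ± 0.04 with shLrp1-1, and the matrix score −0.01 ± 0.01 and −0.23 ± 0.03 (SD, n = 4 each, sh002 mean 0).

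**Figure D4:**
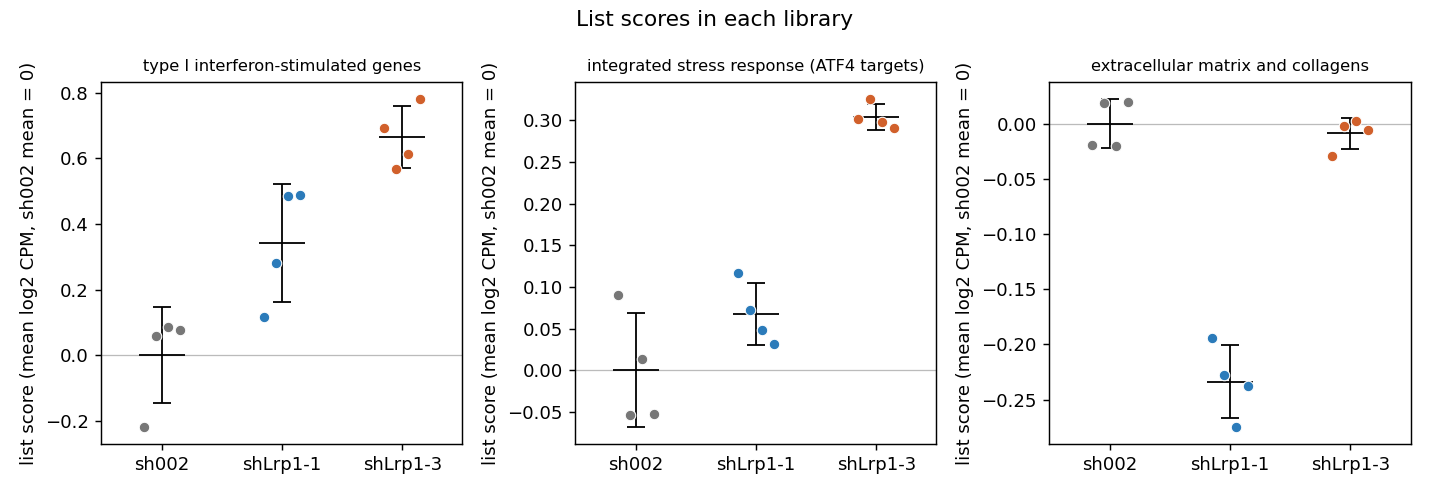
List scores (mean log2 CPM of the members, relative to the sh002 mean) of interferon-stimulated genes, ATF4 targets and matrix genes, with a point per library and bars for the mean ± SD (n = 4). The shLrp1-3 libraries lie at or above 0.291 for ATF4 targets and the other 8 libraries at or below 0.117.

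Among single genes, Sema7a (0.91), Prelp (0.93), Actg2 (0.98) and Inpp5j (0.73) were higher with shLrp1-3, and Il18rap (−1.55), Dennd5b (−1.28), Clec11a (−1.25), Shank2 (−1.15) and the LDL receptor family gene Lrp2 (−0.95) were lower. In all, edgeR called 1962 genes (1119 higher with shLrp1-3, 843 lower), 63 by at least 2-fold (14 higher, 49 lower). The groups did not overlap for 19.4% of genes, where chance gives 2.86%, and fold changes followed GC content across genes (Spearman 0.29, −0.01 with offsets). With library totals in place of TMM, 46.9% of called genes were higher (900 against 1020) in place of 57%. The count was 1226 without shLrp1-1 replicate 3, 1052 without shLrp1-1 replicate 4, 3338 without shLrp1-3 replicate 1, 1285 without shLrp1-3 replicate 2 and 1121 without shLrp1-3 replicate 4. Among the 35 splits of the 8 compared libraries, 7 gave as many lists as the real one with shLrp1-1, 3 with shLrp1-3 and 2 between the hairpins, the real split included, when the correlation was preset. With an estimated correlation only the real split did so in the comparisons with sh002.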

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

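The tests of the hairpin itself for the interferon pattern and of an off-target effect for the stress response pattern were chosen after the results were seen, as were the GC and length offsets. Libraries were compared by Dixon's test, the gap of the lowest or highest of 4 libraries to its nearest neighbour as a share of the range. Chance marks about 1 in 20 groups, and 17 of 363 groups were marked where 5% would be 18.2, so single marks carry little weight.

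Libraries standing apart were, in sh002, replicate 1 for Galnt15 (12.4 CPM, others from 17), Lrp5 (231, others from 280), Herpud1 (94.3, others up to 85) and the score of the interferon-stimulated list (−0.22, others from 0.058), and replicate 3 for Ccl7 (28.4 CPM, others up to 24.2) and Gbp2 (0.94, others up to 0.814). In shLrp1-1, replicate 1 stood apart for Oasl2 (7.44 CPM, others from 10.8), Zbp1 (2.08, others up to 1.93) and Atf5 (81, others up to 69.5). Replicate 4 did so for total counts (76.4 M, others up to 23.3 M), for the Spearman correlation of its deviations with GC content across genes (−0.57, others from 0.19), for Srebf2 (515 CPM, others from 541) and for the scores of cell division (0.072, others up to −0.026) and TGF-beta and YAP targets (0.014, others from 0.029). In shLrp1-3, replicate 4 stood apart for Usp18 (9.6 CPM, others up to 7.03) and the NF-kB score (0.28, others up to 0.216), and replicate 1 for Plat (38 CPM, others from 40.6). The deepest library of shLrp1-1, replicate 4, also decided part of its count of called genes, which was 1819 without it against 2910.

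Results marked because the hairpins differed, by a direct test of shLrp1-3 against shLrp1-1, were the log2 difference of Lrp1 (−0.85), the 1962 called genes and the 9 lists called by camera with a preset correlation, none of which held with an estimated correlation. Their median differences were 0.25 for ATF4 targets, 0.32 for interferon-stimulated genes, 0.23 for antigen presentation, 0.19 for matrix and collagens, 0.39 for fibroblast and pericyte markers, 0.08 for TGF-beta and YAP targets, 0.22 for nuclear-retained RNAs, −0.1 for cell division and 0.02 for the mesenchymal list. With GC and length offsets the last 3 were 0.37 (3 members called in place of 5), −0.05 (9 lower in place of 3) and 0.08.

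Other splits of the same libraries show how often other groupings gave as many calls. For genes, among 35 splits of the 8 libraries, only the real one, 1 split, reached 2910 calls with shLrp1-1 (highest other 0), 2184 with shLrp1-3 (highest other 1230) and 1962 between the hairpins (highest other 0). That is the smallest share 35 splits can give, so it argues against chance without excluding it. Splits also cannot separate the hairpins from other differences between cultures that follow the groups. With GC and length offsets the real split was again the 1 highest, with 3497 (highest other 0), 2900 (792) and 2788 (0). Of 100 splits of the 12 libraries, 1, the real one, gave 1078 shared calls, and the highest other, 819, took the shLrp1-1 libraries as its reference. The splits of the shLrp1-3 and sh002 libraries with 1230 and 886 calls follow the GC-linked component (differences of 13.13 and 16.14, against 0.91 for the real split) and point to a structure of the libraries. Its cause was not tested: with offsets they still gave 425 and 792 calls, and splits that differed by 12.34 and 12.92 gave 0. In the other comparisons the real groups did differ on this component, by 10.16 (shLrp1-1 against sh002) and 9.25 (between the hairpins), so group and component are partly confounded there. What share of the calls comes from it was not measured. Splits that differed more, by 12.36 and 14.77, gave 0 calls, but this cannot decide the question. Like all splits other than the real one, they mix libraries of both groups, so differences between the groups add to their spread. For lists with a preset correlation the splits do not argue against chance: 7 of 35 splits gave at least the 8 lists of shLrp1-1 (highest other 11), 3 of 35 the 12 of shLrp1-3 (13) and 2 of 35 the 9 between the hairpins (9). With an estimated correlation only the real split reached the 4 lists of shLrp1-1 (1 of 35, highest other 1) and the 9 of shLrp1-3 (1 of 35, highest other 0), with the same limits as for genes.

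The first pattern weighed is the rise of interferon-stimulated genes with shLrp1-3 (median log2 fold change 0.60, 29 of 48 called higher), where the list was called in 19 of 34 other splits but in none with as small an adjusted p (for shLrp1-1 against sh002, 10 of 34 others were as small, and between the hairpins 6 of 34). The tables argue against a GC and length trend as the whole cause, since the median was 0.57 with offsets and 29 of 29 members stayed called. They also argue against mixed-in immune cells as the source of the list's summed CPM rise, of which the summed markers rose by 1.43%. This covers shLrp1-3 only: with shLrp1-1 the summed markers rose by 3.91 CPM and the list by 25.2 CPM, a case not weighed. The sums cannot speak for weakly expressed members such as Xaf1 (2.78 CPM in sh002, 7.22 with shLrp1-3), since the summed markers rose by 3.52 CPM. The score of the marker list was also apart from sh002 (0.38 ± 0.08 with shLrp1-3 against 0 ± 0.1, SD, exact permutation p = 0.0286). The low score of sh002 replicate 1 is part of the rise, and without that library the median was 0.50 (camera adjusted p = 1.58e-19). What stays open is a response to the hairpin itself. The list rose more with shLrp1-3 than with shLrp1-1 by 0.32, the order of the Lrp1 knockdown, but either order comes up by chance with 2 hairpins. For this difference, 6 of 34 other splits of the hairpin libraries gave the list as small an adjusted p by camera. A hairpin effect and an effect of Lrp1 loss therefore cannot be told apart.

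The second is the rise of ATF4 target genes with shLrp1-3 (median 0.23 against sh002, and 0.25 against shLrp1-1). The tables argue against a GC and length trend as the whole cause, since the difference between hairpins was 0.22 with offsets and 18 of 20 members stayed called. The rise did not rest on 1 culture, since the lowest shLrp1-3 score (0.291) lay above the highest of the 8 other libraries (0.117). Scores of 12 of 27 lists were apart between the hairpins, however, so this cannot exclude other differences between the sets of cultures. An off-target effect of that hairpin stays open: the list's median was 0.23 with shLrp1-3 and 0.02 with shLrp1-1, and each depth of knockdown has 1 hairpin, so such an effect and a threshold of Lrp1 loss cannot be told apart.

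The third is the lower expression of matrix and collagen genes with shLrp1-1 than with shLrp1-3 (median difference 0.19, 18 of 31 called). The tables argue against a GC and length trend as the whole cause, since the median was 0.17 with offsets and 17 of 18 members stayed called. A smaller share of fibroblast-like cells was predicted to move all called markers alike, and they did not move alike. Of 8 outside the matrix list, 4 were higher with shLrp1-3 (Pdgfrb, Acta2, Cspg4 and Des, the last lost at 0.0508 without the 4 far libraries), 2 lower and 2 not called. The lower ones were Dpt (−0.31), which fell against sh002 with shLrp1-1 (−0.23) and more with shLrp1-3 (−0.54), and Gsn (−0.20, edgeR adjusted p = 0.0492, lost in 12 alternatives with 0.0517 to 0.115); Gsn and Des were named after their values were seen. Single markers can change for other reasons and 4 moved with the matrix genes, so a smaller share of such cells stays open. Also open, untested, is a change within cells, which may follow Lrp1, an off-target effect of shLrp1-1 or differences between the cultures. The list was called lower against sh002 with the weaker knockdown (median −0.20, only −0.08 with offsets, where members called higher went from 2 to 6). It was not called with the stronger one (−0.05, and 0.02 with offsets), an order that 2 hairpins can also give by chance.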

How the results depend on the processing

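The GC and length offsets, the GC-linked score as a covariate and the model without the 4 libraries farthest out were chosen after seeing the data; the other settings were fixed before. No named gene or list was called in the opposite direction in any of them, but with library totals the larger share of called genes turned: 67.5%, 62.2%, 46.9% and 63.9% were higher (shLrp1-1, shLrp1-3, between the hairpins, shared) in place of 43.4%, 47.8%, 57% and 41.6%. TMM factors were 0.9718 to 0.9883 in sh002, 1.008 to 1.03 in shLrp1-1 and 0.9971 to 1.014 in shLrp1-3, so leaving them out raises fold changes against sh002. Why the factors differ was not tested. Lrp1 stayed lower with both hairpins in all settings (leaving out 1 library, −0.95 to −1.06 and −1.80 to −1.90; GC offsets, −0.79 and −1.57). Leaving out 1 library at a time gave 1819 to 3538 genes for shLrp1-1, 1537 to 2412 for shLrp1-3, 1052 to 3338 between the hairpins and 713 to 1348 shared. The counts depended on which library was left out, and the cause was not tested. With the GC-linked score as a covariate the counts for shLrp1-3 and for both hairpins rose to 4536 and 1855, including all 2184 genes called with shLrp1-3 before. The score was taken from the within-group deviations of these same libraries, of whose variance its component held 65.6%. As a covariate it therefore removes, by construction, spread that the tests measure against, and the added calls are not independent support. Other settings kept gene counts within 1.5 times those reported, with 2933, 2205, 2130 and 1083 by DESeq2. With the replicate block they were 2721, 2050, 1594 and 1011, and the dsRNA sensing list was called with shLrp1-3 (camera adjusted p = 0.0456 against 0.236 without it). The labels do not say that the numbers pair the cultures, so no pairing was used in the main model. Same-number libraries correlated at −0.32 to 0.38 (median −0.045). That gives no sign of pairing but cannot exclude it, since the GC-linked component could hide it. Lists called numbered 4 with shLrp1-1 and 0 between the hairpins with an estimated correlation, which asks more of genes that vary together, and 13 with shLrp1-1 by fry, a test of another null hypothesis. By fry and the covariate the cell division difference between hairpins was lost (adjusted p = 0.0568 and 0.0661), and by the covariate and without the 4 far libraries the mesenchymal one (0.0797 and 0.0707). Of 6156 tests of named genes under alternatives, 5982 kept their side of the threshold, 111 lost a call and 63 gained one. Of 1857 tests of lists, 1781 kept it, 26 lost a call and 50 gained one, most often LRP1 ligands (9 settings) and lysosome and endocytosis (7) with shLrp1-1 and mesenchymal genes (7) with shLrp1-3. Depth limits genes near the counting limit, such as Mmp3, whose calls rest on few counts with shLrp1-3.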

Other observations

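The list tests of this part were fixed beforehand, while the GC and length offsets, the GC-linked score as a covariate, the model without the 4 far libraries and the count of Ptprc were chosen after the results were seen. The covariate was taken from the within-group deviations of these same libraries, so calls gained with it are not independent support. Genes of the lysosome and of uptake pathways, in which LRP1 works, were not called as lists in the main tests. With shLrp1-1, 6 of 34 lysosome and endocytosis genes rose and 3 fell (median 0.07, camera adjusted p = 0.0584, but called in 7 alternatives, with 0.00669 to 0.0493, among them without sh002 replicate 3, 0.0124, shLrp1-1 replicate 4, 0.048, or shLrp1-3 replicate 3, 0.0493), and with shLrp1-3, 7 rose and 3 fell (median 0.02, adjusted p = 0.148, but called by fry, 0.024, and without sh002 replicate 3, 0.0324). Ctsb, an abundant lysosomal protease gene, rose with both (log2 fold changes 0.45 and 0.44), although 12.8% of its exonic bases are shared with Fdft1 on the opposite strand, and Lamp1 rose by 0.21 and 0.18. Of 13 LDL receptor family genes, 3 rose and 5 fell with shLrp1-1 (adjusted p = 0.397), and 1 rose and 3 fell with shLrp1-3 (adjusted p = 0.284), while fry called the list with both (0.0175 and 0.0064). With shLrp1-1, Lrp4 rose (0.90) and Lrp5 fell (−0.29), and the list's mean (0.05) and median (−0.07) had opposite signs. LRP1 ligand genes with shLrp1-1 came to 9 higher and 4 lower of 28 (median 0.12, adjusted p = 0.0538). They were called in 9 alternatives (adjusted p from 0.00104 to 0.043), among them GC and length offsets (0.0288), the covariate (0.0228) and leaving out sh002 replicate 3 (0.0306) or shLrp1-1 replicate 3 (0.043) or 4 (0.0112). With an estimated correlation they were not called (camera adjusted p = 0.291). Of 11 cholesterol efflux genes, 2 rose and 2 fell with shLrp1-1 (adjusted p = 0.7), and 1 rose and 3 fell with shLrp1-3 (adjusted p = 0.592), while Npc1, which exports cholesterol from lysosomes, rose by 0.30 with each. Cholesterol biosynthesis genes with shLrp1-3 came to 3 lower and 0 higher of 25 (adjusted p = 0.177, and 0.0486 without sh002 replicate 4).

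Other lists held single genes that changed without a call for the list. Of 34 hypoxia and glycolysis genes, 4 rose and 12 fell with shLrp1-1 (adjusted p = 0.392), including the glycolytic gene Pgam1 (−0.41), and 5 rose and 7 fell with shLrp1-3 (adjusted p = 0.728), including Ndrg1 (0.29) among those higher. Of 15 epithelial genes, 1 rose and 3 fell with shLrp1-1 (adjusted p = 0.581), and 2 rose and 2 fell with shLrp1-3 (adjusted p = 0.627), and Jup, the plakoglobin gene, fell with both (−0.58 and −0.62). Of 23 mesenchymal genes, 5 rose and 5 fell with shLrp1-1 (adjusted p = 0.581), and 9 rose and 3 fell with shLrp1-3 (adjusted p = 0.0783, but called in 7 alternatives, with 0.0064 to 0.0493, among them without sh002 replicate 2, 0.0385, or 3, 0.0252, or shLrp1-3 replicate 1, 0.0493, or 4, 0.0407), and Prrx1, a mesenchymal transcription factor gene, rose with both (0.60 and 0.38). Of 13 Wnt targets, 2 rose and 3 fell with each hairpin (adjusted p = 0.942 and 0.728), with Wnt7b higher with shLrp1-1 (0.35) and Myc higher with shLrp1-3 (0.34). Of 25 unfolded protein response genes, 0 rose and 2 fell with shLrp1-1 (adjusted p = 0.856), and 3 rose and 2 fell with shLrp1-3 (adjusted p = 0.422), including Herpud1 (0.34). Of 32 DNA replication genes, 3 rose and 5 fell with shLrp1-1 (adjusted p = 0.942), and 2 rose and 4 fell with shLrp1-3 (adjusted p = 0.67), with Tk1 lower with both (−0.26 and −0.30). Of 27 dsRNA sensing genes, several of which are interferon-stimulated too, 3 rose and 3 fell with shLrp1-1 (adjusted p = 0.404), and 8 rose and 2 fell with shLrp1-3 (adjusted p = 0.236), including Irf7 (0.82).

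Immune cell markers were few and low. Of 6 tested immune cell markers, 3 rose with shLrp1-1 (median 0.35, adjusted p = 0.0988) and 2 with shLrp1-3 (median 0.31, adjusted p = 0.0688), and none fell. By fry (0.000638 and 0.000214) and without the low-count filter (0.0415 and 0.0473) this list was called with both hairpins, and without sh002 replicate 2 with shLrp1-3 (0.0383). The macrophage marker Cd68 was at 6.78 ± 0.269, 9.89 ± 0.482 and 9.27 ± 0.887 CPM (SD, n = 4 each), while the leukocyte gene Ptprc had 9 counts over all 12 libraries. Ptprc and Ifnb1 were chosen after their values were seen. Of 6 endothelial and adipocyte markers, 3 rose and 1 fell with shLrp1-1 (adjusted p = 0.397, and 0.0333 without sh002 replicate 2), and 2 rose and 0 fell with shLrp1-3 (adjusted p = 0.292, and 0.0301 by fry). Fibroblast and pericyte markers with shLrp1-3 came to 3 higher and 2 lower of 11 (adjusted p = 0.909), and matrix and collagen genes to 5 higher and 8 lower of 31 (median −0.05, adjusted p = 0.292).

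Besides LRP1 ligands, given above, 6 lists were called with shLrp1-3 and not with shLrp1-1, with these values for shLrp1-1. Antigen presentation genes came to 5 higher and 5 lower of 30 (adjusted p = 0.174, and 0.0355 without shLrp1-1 replicate 1), ATF4 targets to 8 higher and 2 lower of 31 (adjusted p = 0.186, and 0.0366 without shLrp1-1 replicate 4), p53 targets to 7 higher and 2 lower of 26 (adjusted p = 0.103, and 0.001 by fry), TGF-beta and YAP targets to 5 higher and 3 lower of 30 (median −0.06 but mean 0.03, adjusted p = 0.607), cell division genes to 0 higher and 8 lower of 32 (median 0.01 but lower by camera, adjusted p = 0.397), and nuclear-retained RNAs to 2 higher and 0 lower of 12 (adjusted p = 0.397). Cell division genes were, however, called lower with shLrp1-1 too with GC and length offsets (13 lower, median −0.09, adjusted p = 0.0288), with the covariate (0.000422) and without the 4 far libraries (0.0334). These camera calls used the preset correlation. In the main model the list was not called with an estimated correlation (camera adjusted p = 0.739). Between the hairpins, neither p53 targets (adjusted p = 0.0972, but 0.035 without shLrp1-3 replicate 1, 0.0083 without the 4 far libraries and 0.00128 by fry) nor LRP1 ligand genes (adjusted p = 0.103, but 0.0499 without shLrp1-1 replicate 1 and 0.00995 by fry) were called as lists in the main tests. The mitochondrially encoded list had 0 of its members in the count table.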
